A study of Mus musculus with 12 samples.

How the data were processed

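RNA from whole lung of 12 mice was hybridised to one-colour Affymetrix arrays, 1 array per mouse, with 3 mice in each of 4 groups (wild type and Zmpste24-/-, baseline and ventilated). Group and replicate number were taken from the sample labels. RNA was extracted with Trizol and 100 ng were labelled, per the labels' protocols. The authors deposited normalized expression values on a log2 scale; RMA and limma are named per the submitters' processing notes, and their versions are not given in the sources used here. The log2 scale was inferred from the range of the deposited values. Array medians were 5.40, 5.40 and 5.39 in wild type baseline lungs, 5.35, 5.39 and 5.38 in Zmpste24-/- baseline lungs, 5.42, 5.42 and 5.42 in wild type ventilated lungs and 5.35, 5.36 and 5.38 in Zmpste24-/- ventilated lungs. No scan date or slide is given in the sources used here, so array batches were not tested.

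Of the 41345 probes, 23521 were paired with 1 gene symbol, 1814 with several and 16010 with none in the platform annotation used here, so the last are unnamed here. Symbols were checked against a RefSeq gene table (assembly GRCm38.p6), in which 23328 of the 1-symbol probes matched by gene identifier and 193 did not. The table was used for names, gene types, gene neighbours and the host genes of small nucleolar RNAs. For these 193 the annotation's symbol was kept. No coordinates are given because the genome build of the probes is not given in the sources used here. Each gene was represented by its 1-symbol probe with the highest mean over the 12 arrays, which left 22180 genes, 1082 of them with more than 1 probe. Probes of one gene passed in opposite directions in 1 gene for ventilation in wild type lungs, 4 for ventilation in Zmpste24-/- lungs, and 1 and 2 for genotype at baseline and under ventilation, in a limma fit of the 1-symbol probes. For the interaction 6 genes with several probes had a probe that passed in that fit, none of them in both directions.

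Values were not normalized again. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom before moderation), and 5 contrasts were taken: ventilated minus baseline in each genotype, Zmpste24-/- minus wild type in each condition, and the interaction. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and an adjusted p under 0.05 counted as passed. Chance alone separates 10% of genes completely with 3 arrays against 3. The genes that passed and did not overlap between the groups numbered 1578, 3597, 1395 and 2365 in the 4 pairwise contrasts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. With 3 arrays per group an exact permutation test of a single gene cannot give a p below 0.1, so the gene tests rest on limma's shared variance model.

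Before the data were examined, the model, the threshold, the alternatives, the 31 gene lists and the rule for named genes were fixed. The rule names Zmpste24 and Lmna, the 10 genes with the largest increase and the 10 with the largest decrease in each pairwise contrast among those that passed without overlap of arrays, the 10 interaction genes with the smallest adjusted p, and up to 4 members of each list with the smallest adjusted p. Predicted or unnamed genes, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors and antigen receptor segments were tested but not taken into the 10 and 10. The values of Adm, Nfil3 and the other interaction genes in the single ventilation comparisons, and single array values of Alb, Mup20, Cyp4a14 and Hspa1b, were added after the interaction and the arrays had been seen.

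The lists were p53 targets, inflammatory cytokines and NF-kB targets, immediate early genes, YAP and TAZ targets, interferon-stimulated genes, glucocorticoid-induced genes, circadian clock, NRF2 targets, heat shock proteins, unfolded protein and integrated stress response, hypoxia-induced genes, collagens and matrix, cell cycle, nuclear lamina and prelamin A processing, senescence and its secretome, insulin-like growth factor axis, and small nucleolar RNAs as a sign of RNA quality. Cell type lists were alveolar type 2, alveolar type 1, club and ciliated airway, endothelial, fibroblast and smooth muscle, neutrophil, macrophage and monocyte, B, T and NK cells, thymocytes, red cells and platelets, cardiac and skeletal muscle, adipocytes, and squamous epithelium and mesothelium. List members were counted past the threshold over all genes and adjusted over the list alone. Each list was compared with all other genes by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, each adjusted over the 31 lists of a contrast. Fry tests whether the genes of a list move on balance in one direction, and does not compare the list with other genes.

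The alternatives were: leaving out genes under the 25th percentile or the median of mean expression, subtracting each array's median, a second quantile normalization, cyclic loess, eBayes with trend and robust estimation, array weights, fitting the 2 compared groups alone, testing all probes, averaging the probes of a gene, keeping probes with several symbols under the first, the replicate number as a block, a minimum of 2-fold, and leaving out each array in turn. The list counts without wild type baseline array 2, and the clock score with each array left out, were added after the data were seen. On simulated data for ventilation in wild type lungs, the model recovered 68.1% of 91 genes changed by 0.5 on the log2 scale, 98.4% of 62 changed by 1 and 100% of 67 changed by 2, with 7 of 21960 unchanged genes passing. For the interaction the shares recovered were 15.4%, 88.7% and 100%. The simulation used wild type baseline means and independent normal noise with the model's moderated spreads, equal in all groups. It holds no correlation between genes and no outlying array, so these shares may not carry over to the real arrays. The overlap of calls between 2 contrasts was set against the product of their calls divided by the genes tested.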

Results

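Gene expression was measured in whole lung from 12 female mice aged 10 weeks, 1 one-colour Affymetrix array per mouse. The mice were wild type or lacked Zmpste24 (Zmpste24-/-), the metalloprotease that cuts the farnesylated precursor of lamin A. Each genotype was sampled intact (baseline) or after mechanical ventilation, with 3 mice in each of the 4 groups. Ventilation lasted 2.5 hours at an inspiratory pressure of 15 cmH2O without end-expiratory pressure, at 100 breaths per minute and an inspired oxygen fraction of 0.21. The deposited log2 values of single arrays had medians between 5.35 and 5.42. Correlations across probes, which are not independent replicates, were 0.986 to 0.992 between arrays of one group and 0.970 to 0.988 between arrays of different groups. Precision was limited by the number of arrays, 3 per group.

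The targeted gene was low in every Zmpste24-/- array. Zmpste24 stood at 9.0, 9.02 and 8.50 in wild type baseline lungs and 8.50, 9.28 and 8.91 in wild type ventilated lungs (log2 values of arrays 1 to 3). It stood at 5.91, 5.31 and 5.44 in Zmpste24-/- baseline lungs and 5.01, 5.73 and 5.43 in Zmpste24-/- ventilated lungs. The genotype difference in Zmpste24 was -3.29 ± 0.22 at baseline (adjusted p = 1.18e-05) and -3.51 ± 0.22 under ventilation (adjusted p = 5.57e-06), as log2 fold change ± standard error from limma. The values in Zmpste24-/- lungs lay near the array medians and no background level was set, so the size of the difference is uncertain. Where the probes of Zmpste24 lie relative to the deleted part of the gene is not given in the sources used here. Lmna, which encodes lamin A and its precursor, averaged 7.48 ± 0.20 and 7.52 ± 0.19 (SD, n = 3) at baseline in wild type and Zmpste24-/- lungs, and 7.78 ± 0.09 and 8.06 ± 0.06 after ventilation. Ventilation raised Lmna (0.55 ± 0.11) in Zmpste24-/- lungs, where the adjusted p was 0.00497. Its change in wild type lungs, 0.31 ± 0.11, and its genotype differences, 0.04 ± 0.11 at baseline and 0.28 ± 0.11 under ventilation, did not pass the threshold.

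**Figure D1:**
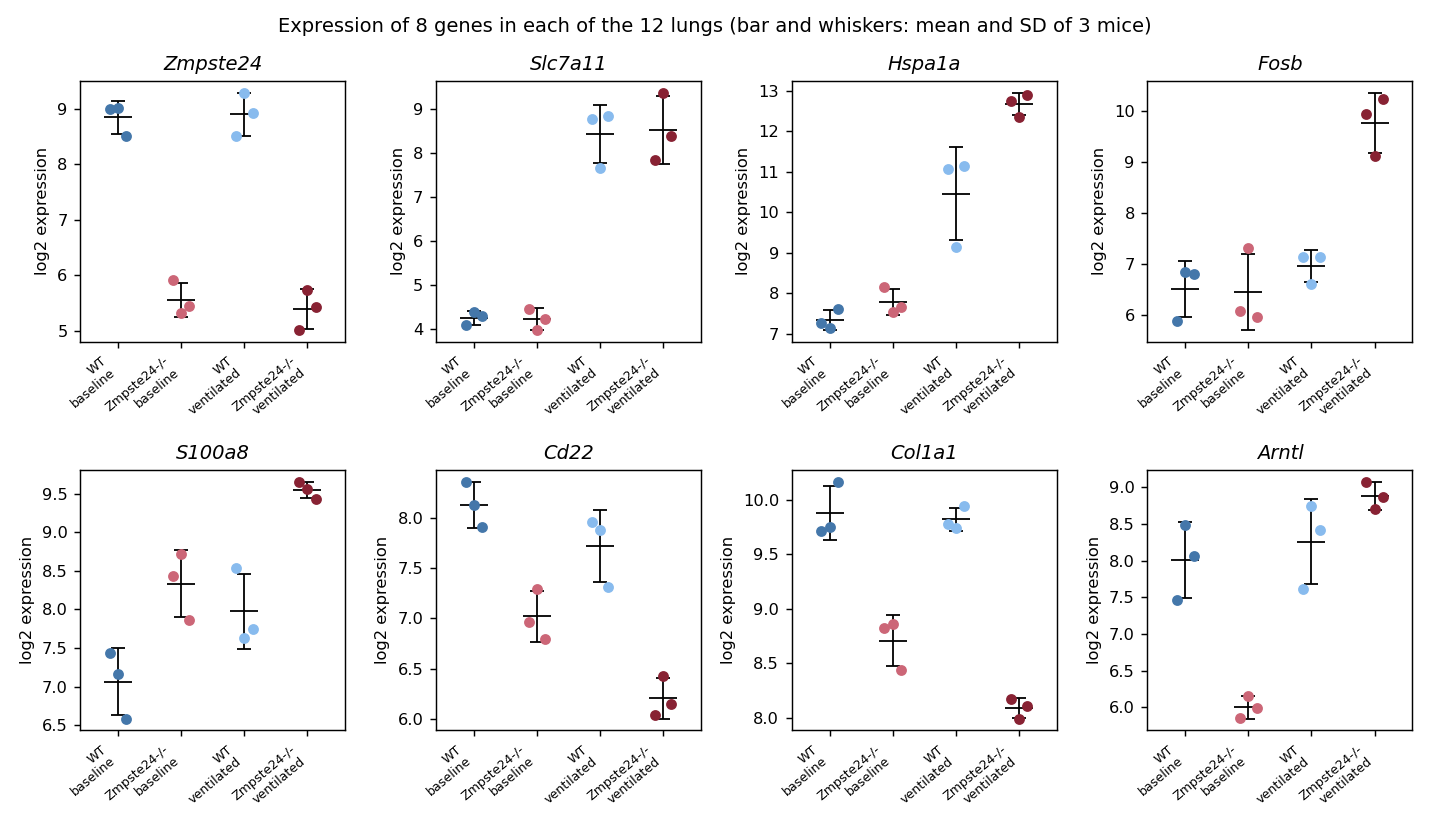
Log2 expression (vertical axes) of 8 genes in each of the 12 lungs, by group (horizontal axes), with each point 1 mouse and bars and whiskers the mean and SD of 3 mice. All 6 Zmpste24-/- arrays lie at or below 5.91 for Zmpste24 and all 6 wild type arrays at or above 8.50.

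The first comparison asked how ventilation changed wild type lungs. Stress and antioxidant genes led the increases in ventilated wild type lungs: Slc7a11 (4.18 ± 0.34), the cystine and glutamate exchanger, came first, followed by the inducible heat shock proteins Hspa1b (4.03 ± 0.52) and Hspa1a (3.11 ± 0.40) (log2 fold change ± standard error, n = 3 per group, here and for all genes that follow). Also higher were Ptgs2 (2.63 ± 0.27), the inducible cyclooxygenase, the metallothionein Mt2 (2.55 ± 0.19), the stress transcription factor Atf3 (2.48 ± 0.25) and Hmox1 (2.36 ± 0.30), which degrades heme. Cldn4 (2.32 ± 0.27), Sprr1a (2.22 ± 0.34) and Pdk4 (2.20 ± 0.29) completed the 10 largest named increases. Among the decreases were the endothelial genes Tmem100 (-1.95 ± 0.12), Sox18 (-1.49 ± 0.16) and Edn1 (-1.41 ± 0.23), the flow-responsive factor Klf2 (-1.53 ± 0.16) and the transcription factors Meox2 (-1.54 ± 0.10), Foxf2 (-1.34 ± 0.12) and Prdm8 (-1.36 ± 0.16). As the naming rule required, the 3 ventilated and 3 baseline arrays did not overlap in any of these genes. No background level was set. The size of a change is therefore uncertain, here and below, wherever a compared group lies under the array medians. Slc7a11 did so at baseline (4.08, 4.38 and 4.28). Hspa1a and Hspa1b are near-identical copies and their separate values are uncertain. The spread of Hspa1b was wide after ventilation, with 8.11 in wild type ventilated array 2 against 10.69 and 10.68 in the others. The abundant liver transcripts Mup20 (-3.63 ± 0.77) and Cyp4a14 (-2.01 ± 0.52) also fell in ventilated lungs. Without wild type baseline array 2 the changes were -2.38 and -1.08 and passed (limma adjusted p = 0.0075 and 0.00237). Their highest values, 10.05 and 7.43, were those of that array, against at most 6.44 and 4.82 in any other array. Mup20 lost its call without wild type ventilated array 3 (adjusted p = 0.0572), and Cyp4a14 lost it without wild type ventilated array 1, 2 or 3 (adjusted p = 0.0753, 0.0623 and 0.119). Ifi208 (-1.35 ± 0.34) was the last of the 10 largest named decreases, and lost its call without wild type baseline array 2 or ventilated array 1, 2 or 3 (adjusted p = 0.0694, 0.0726, 0.0595 and 0.0925).

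Of the gene groups fixed before the data were examined, targets of NRF2, the antioxidant response factor, had the highest list median in ventilated wild type lungs: 11 of 14 rose and the others did not pass (12 higher and 0 lower adjusted over the list alone), among them Gclc (1.94 ± 0.17) and Txnrd1 (1.52 ± 0.14). The median, 0.98, came with a camera adjusted p of 2.95e-15 (adjusted p = 0.0979 with an estimated correlation). Glucocorticoid-induced genes rose in 9 of 17 members (10 higher and 0 lower adjusted over the list alone), with Zbtb16 (1.74 ± 0.21), Fkbp5 (1.59 ± 0.17) and Mt1 (1.54 ± 0.11). Their median was 0.63 and the camera adjusted p 5.95e-11 (adjusted p = 0.0979 with an estimated correlation). Inflammatory cytokines and NF-kB targets rose in 9 of 28 members (12 higher and 0 lower adjusted over the list alone), including Birc3 (0.83 ± 0.09), Nfkb2 (0.84 ± 0.10) and Relb (0.76 ± 0.09). The median, 0.34, came with a camera adjusted p of 6.59e-11 (adjusted p = 0.0979 with an estimated correlation). The unfolded protein and integrated stress response had 7 of 16 members higher (9 higher and 0 lower adjusted over the list alone, 4 to 7 with 1 array left out, lowest without wild type baseline array 1), with Chac1 (1.91 ± 0.22), Atf4 (0.96 ± 0.11) and Asns (0.93 ± 0.12). Their median was 0.31 and the camera adjusted p 1.36e-08 (adjusted p = 0.0979 with an estimated correlation). Heat shock proteins rose in 5 of 12 (7 higher and 1 lower adjusted over the list alone, 2 to 6 with 1 array left out, lowest without wild type ventilated array 1). The median, 0.52, came with a camera adjusted p of 2.18e-06 (adjusted p = 0.222 with an estimated correlation). Immediate early genes rose in 7 of 22 (11 higher and 2 lower adjusted over the list alone), with Maff (1.43 ± 0.16), Myc (1.37 ± 0.17) and Nr4a3 (1.32 ± 0.23). Their median was 0.45 and the camera adjusted p 2.18e-06 (adjusted p = 0.332 with an estimated correlation). Hypoxia-induced genes rose in 5 of 14 (7 higher and 0 lower adjusted over the list alone), with Adm (1.18 ± 0.17), Hk2 (1.17 ± 0.14) and Bnip3 (0.57 ± 0.10). The median, 0.26, came with a camera adjusted p of 3.2e-05 (adjusted p = 0.0979 with an estimated correlation). Among p53 targets 5 of 22 rose (7 higher and 0 lower adjusted over the list alone, 3 to 6 with 1 array left out, lowest without wild type ventilated array 2), with the cell cycle inhibitor Cdkn1a (1.52 ± 0.20) and Sesn2 (1.15 ± 0.16) and Aen (0.47 ± 0.10). Their median was 0.15 and the camera adjusted p 0.00156 (adjusted p = 0.0979 with an estimated correlation). Senescence genes rose in 3 of 15 (5 higher and 1 lower adjusted over the list alone), with Plaur (1.34 ± 0.19). The median, 0.31, came with a camera adjusted p of 0.00335 (adjusted p = 0.123 with an estimated correlation).

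Among markers of lung cell types, endothelial genes fell in 11 of 16 members in ventilated wild type lungs (0 higher and 16 lower adjusted over the list alone, 6 to 10 with 1 array left out, lowest without wild type baseline array 2), with Cldn5 (-0.87 ± 0.11), Gpihbp1 (-0.67 ± 0.12), Ednrb (-0.65 ± 0.11) and Tek (-0.63 ± 0.11). Their median was -0.48 and the camera adjusted p 7.59e-13 (adjusted p = 0.0979 with an estimated correlation). Fibroblast and smooth muscle genes fell in 6 of 14 (0 higher and 6 lower adjusted over the list alone, 2 to 5 with 1 array left out, lowest without wild type ventilated array 3), with Tcf21 (-1.0 ± 0.11) and Wnt2 (-0.82 ± 0.10). The median, -0.07, came with a camera adjusted p of 0.0037 (adjusted p = 0.295 with an estimated correlation). Neutrophil genes rose in 5 of 15 (7 higher and 0 lower adjusted over the list alone, 2 to 5 with 1 array left out, lowest without wild type baseline array 2), with Il1r2 (1.56 ± 0.27) and Clec4d (0.96 ± 0.17). Their median was 0.63 and the camera adjusted p 2.18e-06 (adjusted p = 0.158 with an estimated correlation). Interferon-stimulated genes fell in 4 of 22 (1 higher and 8 lower adjusted over the list alone), with Xaf1 (-0.75 ± 0.11), Rsad2 (-0.72 ± 0.14) and Rtp4 (-0.54 ± 0.11). The median, -0.25, came with a camera adjusted p of 1.31e-05 (adjusted p = 0.11 with an estimated correlation). T and NK cell genes fell in 3 of 20 (1 higher and 5 lower adjusted over the list alone, 1 to 3 with 1 array left out, lowest without wild type ventilated array 1), with Nkg7 (-0.79 ± 0.12), and B cell genes in 1 of 12 (0 higher and 1 lower adjusted over the list alone, 0 to 2 with 1 array left out, lowest without wild type baseline array 1). For T and NK cells the median was -0.22 and the camera adjusted p 0.00111 (adjusted p = 0.186 with an estimated correlation). For B cells the median was -0.42 and the camera adjusted p 0.00066 (adjusted p = 0.385 with an estimated correlation). Small nucleolar RNAs rose in 6 of 73 (13 higher and 0 lower adjusted over the list alone, 2 to 6 with 1 array left out, lowest without wild type ventilated array 2). Their median was 0.18 and the camera adjusted p 6.64e-06 (adjusted p = 0.295 with an estimated correlation). No squamous or mesothelial gene of 11 passed, although the list as a whole lay lower (0 higher and 0 lower adjusted over the list alone). The median, -0.32, came with a camera adjusted p of 0.0236 (adjusted p = 0.378 with an estimated correlation). YAP and TAZ targets went both ways, 5 higher and 1 lower of 22 (5 higher and 3 lower adjusted over the list alone, 2 to 3 with 1 array left out, lowest without wild type baseline array 1), with F3 (1.98 ± 0.17) against Foxf2 (-1.34 ± 0.12). Their median was -0.01 and the camera adjusted p 0.713 (adjusted p = 0.863 with an estimated correlation). The insulin-like growth factor axis also went both ways, 1 higher and 2 lower of 15 (1 higher and 2 lower adjusted over the list alone, 0 to 2 with 1 array left out, lowest without wild type ventilated array 1). The median, -0.11, came with a camera adjusted p of 0.269 (adjusted p = 0.574 with an estimated correlation).

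Without wild type baseline array 2, the array with the high liver transcripts, NRF2 targets were higher in 9, glucocorticoid-induced genes in 8, NF-kB targets in 7, unfolded protein response genes in 4, heat shock proteins in 3 and neutrophil genes in 2 members, and endothelial genes lower in 6 and fibroblast genes in 4. The squamous and mesothelial list then missed the threshold (camera adjusted p = 0.191), as it did without wild type ventilated array 1 (0.222), and the fibroblast list missed it without wild type ventilated array 3 (0.0522). In all, 1597 of 22180 genes passed an adjusted p of 0.05 in wild type lungs, 815 higher and 782 lower, and 131 of these changed at least 2-fold. With each array's median subtracted the balance turned to 681 higher and 883 lower. The 1597 became 1072 without wild type baseline array 2, 799 without wild type ventilated array 3 and 923 with the 2 compared groups fitted alone.

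In Zmpste24-/- lungs the same comparison gave more genes past the threshold in total (3641 against 1597), though not in every gene list. The largest increases after ventilation were Hspa1b (5.47 ± 0.52) and Hspa1a (4.88 ± 0.40), at 44.4-fold and 29.5-fold, Ptgs2 (4.43 ± 0.27), Slc7a11 (4.30 ± 0.34) and Atf3 (4.01 ± 0.25). They were followed by the chemokine Ccl3 (3.55 ± 0.36), the vasodilator peptide precursor Adm (3.44 ± 0.17), the AP-1 subunit Fosb (3.31 ± 0.36), Chac1 (3.29 ± 0.22), which degrades glutathione, and the acute-phase gene Saa3 (3.26 ± 0.32). The largest decreases were the clock output genes Dbp (-2.86 ± 0.39) and Per3 (-2.22 ± 0.28), Lrat (-1.81 ± 0.30), which esterifies retinol, Tmem100 (-1.71 ± 0.12), Chad (-1.64 ± 0.34), Cckar (-1.53 ± 0.16) and Lbh (-1.48 ± 0.11), and Bbof1 (-1.42 ± 0.22) and Sntn (-1.41 ± 0.16), known from motile cilia. Gbp4 (-1.54 ± 0.40) belonged to the same 10 but lost its call without Zmpste24-/- baseline array 1 or ventilated array 1 (adjusted p = 0.0806 and 0.0673). By the naming rule, the 3 ventilated and 3 baseline arrays did not overlap in any of these genes.

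Immediate early genes rose in 20 of 22 members in ventilated Zmpste24-/- lungs (21 higher and 0 lower adjusted over the list alone), with Myc (2.57 ± 0.17), Maff (1.54 ± 0.16) and Klf6 (0.98 ± 0.10). Their median was 1.59 and the camera adjusted p 1.57e-23 (adjusted p = 0.0817 with an estimated correlation). Heat shock proteins rose in 11 of 12 (11 higher and 0 lower adjusted over the list alone), among them Dnajb1 (3.07 ± 0.22) and Hsp90aa1 (1.27 ± 0.12). The median, 1.27, came with a camera adjusted p of 4.81e-13 (adjusted p = 0.0947 with an estimated correlation). Inflammatory cytokines and NF-kB targets rose in 18 of 28 (22 higher and 0 lower adjusted over the list alone), with Tnfaip3 (1.25 ± 0.10), Icam1 (0.93 ± 0.08) and Birc3 (0.92 ± 0.09). Their median was 0.68 and the camera adjusted p 2.62e-15 (adjusted p = 0.0511 with an estimated correlation). The unfolded protein and integrated stress response had 10 of 16 members higher (12 higher and 0 lower adjusted over the list alone), with Atf4 (1.51 ± 0.11), Ppp1r15a (1.44 ± 0.14) and Ddit3 (1.07 ± 0.08). The median, 0.73, came with a camera adjusted p of 3.56e-11 (adjusted p = 0.0817 with an estimated correlation). NRF2 targets rose in 9 of 14 and fell in 1 (10 higher and 1 lower adjusted over the list alone), with Srxn1 (2.48 ± 0.23), Gclc (2.17 ± 0.17) and Txnrd1 (1.76 ± 0.14). Their median was 0.82 and the camera adjusted p 9.83e-09 (adjusted p = 0.183 with an estimated correlation). Glucocorticoid-induced genes rose in 8 of 17 and fell in 1 (9 higher and 1 lower adjusted over the list alone), with Pdk4 (2.40 ± 0.29) and Mt2 (2.16 ± 0.19). The median, 0.56, came with a camera adjusted p of 1.71e-05 (adjusted p = 0.226 with an estimated correlation). Among p53 targets 8 of 22 rose and 1 fell (8 higher and 1 lower adjusted over the list alone), with Cdkn1a (2.78 ± 0.20), Sesn2 (1.86 ± 0.16) and Tnfrsf10b (0.99 ± 0.12). Their median was 0.21 and the camera adjusted p 0.000235 (adjusted p = 0.0817 with an estimated correlation). Senescence genes rose in 6 of 15 and fell in 1 (8 higher and 1 lower adjusted over the list alone), with Il6 (2.17 ± 0.30, from baseline values under the array medians), Plaur (1.98 ± 0.19) and Timp1 (0.97 ± 0.14). The median, 0.57, came with a camera adjusted p of 1.75e-05 (adjusted p = 0.0817 with an estimated correlation). Hypoxia-induced genes rose in 7 of 14 and fell in 1 (7 higher and 1 lower adjusted over the list alone), with Slc2a1 (1.14 ± 0.15) against Pdk1 (-0.63 ± 0.11). Their median was 0.32 and the camera adjusted p 0.000116 (adjusted p = 0.118 with an estimated correlation). Clock genes went both ways, 5 higher and 8 lower of 16 (6 higher and 8 lower adjusted over the list alone), with the activators Arntl (2.88 ± 0.26) and Clock (0.75 ± 0.10) higher. The median, -0.43, came with a camera adjusted p of 0.509 (adjusted p = 0.773 with an estimated correlation).

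Neutrophil genes rose in 10 of 15 members in ventilated Zmpste24-/- lungs (11 higher and 0 lower adjusted over the list alone), with Il1r2 (2.40 ± 0.27), Mmp8 (2.32 ± 0.27) and Clec4d (1.98 ± 0.17). Their median was 1.02 and the camera adjusted p 5.16e-08 (adjusted p = 0.118 with an estimated correlation). B cell genes fell in 8 of 12 (0 higher and 10 lower adjusted over the list alone, 4 to 8 with 1 array left out, lowest without Zmpste24-/- ventilated array 1), with Ighm (-0.91 ± 0.20), Bank1 (-0.90 ± 0.21) and Cd22 (-0.81 ± 0.18). The median, -0.67, came with a camera adjusted p of 2.52e-06 (adjusted p = 0.263 with an estimated correlation). Endothelial genes fell in 9 of 16 (0 higher and 11 lower adjusted over the list alone, 4 to 9 with 1 array left out, lowest without Zmpste24-/- baseline array 3), with Cldn5 (-0.68 ± 0.11), Emcn (-0.54 ± 0.10) and Tek (-0.55 ± 0.11). Their median was -0.33 and the camera adjusted p 9.89e-07 (adjusted p = 0.17 with an estimated correlation). Club and ciliated airway cell genes fell in 8 of 20 (0 higher and 10 lower adjusted over the list alone, 2 to 10 with 1 array left out, lowest without Zmpste24-/- baseline array 1), with Dnah5 (-0.80 ± 0.19). The median, -0.44, came with a camera adjusted p of 1.84e-05 (adjusted p = 0.365 with an estimated correlation). Collagen and matrix genes fell in 9 of 22 and rose in 3 (3 higher and 9 lower adjusted over the list alone), with Col6a3 (-0.95 ± 0.15) and Col1a2 (-0.71 ± 0.09) against Lox (1.22 ± 0.16). Their median was -0.21 and the camera adjusted p 0.00692 (adjusted p = 0.365 with an estimated correlation). Interferon-stimulated genes fell in 6 and rose in 1 of 22 (1 higher and 8 lower adjusted over the list alone), with Gbp3 (-0.84 ± 0.19) and Rtp4 (-0.81 ± 0.11). The median, -0.17, came with a camera adjusted p of 0.00205 (adjusted p = 0.234 with an estimated correlation). Fibroblast and smooth muscle genes fell in 2 of 14 (0 higher and 2 lower adjusted over the list alone), with Inmt (-0.75 ± 0.13) and Wnt2 (-0.61 ± 0.10). Their median was -0.25 and the camera adjusted p 0.0108 (adjusted p = 0.364 with an estimated correlation). Small nucleolar RNAs rose in 4 and fell in 3 of 73 (3 higher and 3 lower adjusted over the list alone, 2 to 4 with 1 array left out, lowest without Zmpste24-/- baseline array 3). The median, -0.16, came with a camera adjusted p of 0.0302 (adjusted p = 0.659 with an estimated correlation). The nuclear lamina and prelamin A processing list had 2 members higher and 1 lower of 15 (2 higher and 1 lower adjusted over the list alone), with Lbr (0.40 ± 0.09), the lamin B receptor, against Syne1 (-0.45 ± 0.10). Their median was 0.11 and the camera adjusted p 0.226 (adjusted p = 0.568 with an estimated correlation). Thymocyte genes, with 6 measured, had none past the threshold (0 higher and 0 lower adjusted over the list alone). The median, 0.04, came with a camera adjusted p of 0.648 (adjusted p = 0.793 with an estimated correlation).

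Of the lists called in ventilated Zmpste24-/- lungs, fibroblasts and smooth muscle missed the threshold without Zmpste24-/- baseline array 1 (camera adjusted p = 0.11). Small nucleolar RNAs missed it without Zmpste24-/- baseline array 2 (0.246) or ventilated array 3 (0.334). In total 3641 genes passed in Zmpste24-/- lungs, 1972 higher and 1669 lower, and 331 changed at least 2-fold. The total was 2432 to 3165 with 1 array left out. Between the genotypes, whose ventilation comparisons share no arrays, 606 genes rose in both (72.5 from independent lists), 447 fell in both (58.8) and 3 moved in opposite directions (131). Across genes, which are not independent replicates, the ventilation log2 fold changes of the 2 genotypes correlated with Pearson's r of 0.618 and Spearman's rho of 0.481.

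**Figure D2:**
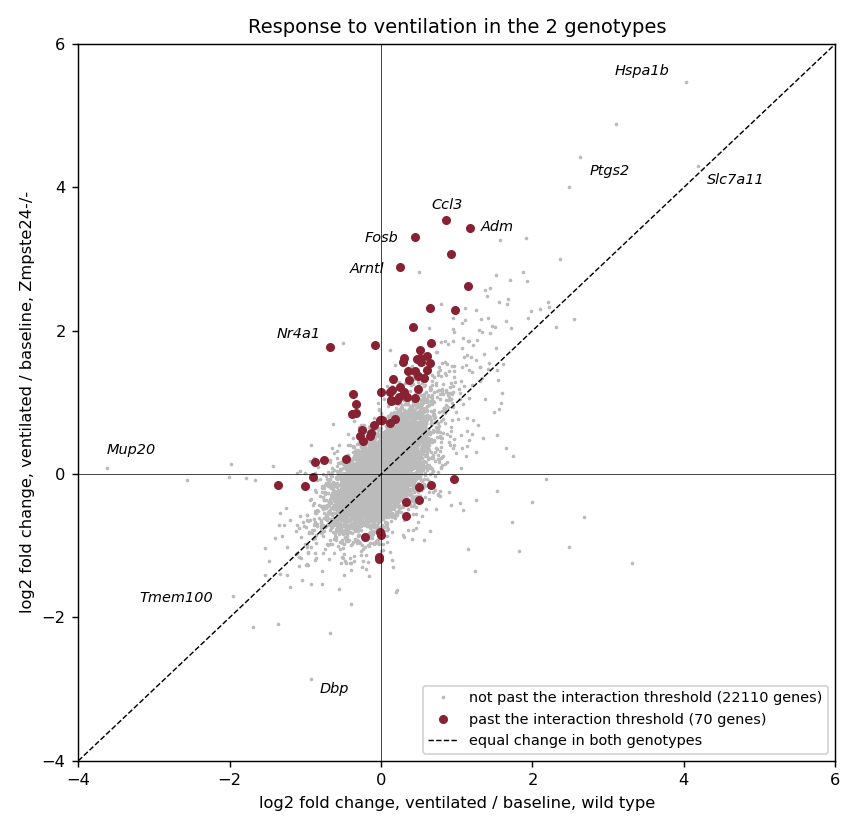
Log2 fold change on ventilation in wild type lungs (horizontal axis) against that in Zmpste24-/- lungs (vertical axis), 1 point per gene, with the 70 genes past the interaction threshold in dark red and a dashed line of equal change. Of these 70, 40 lie in the upper right with the larger change in Zmpste24-/- lungs.

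The genotype comparison at baseline asked what differed between lungs that had not been ventilated. Besides Zmpste24 itself, intact Zmpste24-/- lungs had less of the clock activator Arntl (-2.01 ± 0.26) and of genes of cytotoxic lymphocytes, Gzma (-1.78 ± 0.23), Ncr1 (-1.69 ± 0.22) and Ccl5 (-1.63 ± 0.14), as well as Spon2 (-1.56 ± 0.28). Higher in Zmpste24-/- lungs were Stfa2l1 (2.34 ± 0.37), of the stefin family of protease inhibitors, the transcription factor Zbtb16 (1.49 ± 0.21), Akr1c14 (1.49 ± 0.15), the clock gene Per3 (1.40 ± 0.28), Ptcd3 (1.33 ± 0.20) and small noncoding RNAs, Scarna6 (1.92 ± 0.17), Rny1 (1.46 ± 0.20) and Rny3 (1.38 ± 0.24). Lower in Zmpste24-/- lungs were also the liver transcripts Mup20 (-4.49 ± 0.77), Alb (-3.44 ± 0.65), Mup3 (-3.15 ± 0.66) and Cyp4a14 (-1.91 ± 0.52). All 4 had their highest value in wild type baseline array 2, without which Mup20 differed by -3.24, Alb by -2.49, Mup3 by -2.24 and Cyp4a14 by -0.98. Without that array all 4 passed (limma adjusted p = 0.00224, 0.0112, 0.0281 and 0.00661). Alb stood at 11.52 in that array, at 8.12 and 9.18 in the other wild type baseline lungs and between 6.04 and 6.39 in Zmpste24-/- baseline lungs. Sult1d1 (1.82 ± 0.47) and Chp1 (1.60 ± 0.44) were also among the 10 largest increases, but their calls were lost when single arrays were left out (adjusted p up to 0.123 and 0.142), as was that of Cyp4a14 (up to 0.141). The Zmpste24-/- values of Mup20, Mup3 and Cyp4a14 lay under the array medians, so the size of their differences is uncertain. Members of the Mup and stefin families are near-identical copies whose separate values are uncertain.

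T and NK cell genes fell in 13 of 20 members in intact Zmpste24-/- lungs (0 higher and 18 lower adjusted over the list alone), with Gzmb (-1.25 ± 0.12), Nkg7 (-1.10 ± 0.12), Klre1 (-1.01 ± 0.11) and Cd2 (-0.82 ± 0.09). Their median was -0.72 and the camera adjusted p 3.82e-18 (adjusted p = 0.0185 with an estimated correlation). B cell genes fell in 8 of 12 (0 higher and 11 lower adjusted over the list alone, 3 to 11 with 1 array left out, lowest without wild type baseline array 1), with Cd22 (-1.11 ± 0.18), Blk (-0.98 ± 0.15) and Spib (-0.83 ± 0.16). The median, -0.76, came with a camera adjusted p of 7.05e-10 (adjusted p = 0.187 with an estimated correlation). Collagen and matrix genes fell in 12 of 22 (1 higher and 15 lower adjusted over the list alone), with the matrix protease Mmp2 (-1.33 ± 0.17) and the fibrillar collagens Col3a1 (-1.20 ± 0.16), Col1a1 (-1.17 ± 0.13) and Col1a2 (-0.83 ± 0.09). Their median was -0.43 and the camera adjusted p 3.57e-12 (adjusted p = 0.0526 with an estimated correlation). Interferon-stimulated genes fell in 10 of 22 (0 higher and 14 lower adjusted over the list alone, 6 to 10 with 1 array left out, lowest without Zmpste24-/- baseline array 3), with Oas2 (-1.33 ± 0.12), Irf7 (-0.66 ± 0.09) and Xaf1 (-0.63 ± 0.11). The median, -0.41, came with a camera adjusted p of 8.5e-10 (adjusted p = 0.0526 with an estimated correlation). Endothelial genes fell in 8 of 16 (0 higher and 12 lower adjusted over the list alone, 3 to 6 with 1 array left out, lowest without wild type baseline array 2), with Plvap (-1.0 ± 0.17) and Emcn (-0.53 ± 0.10). Their median was -0.39 and the camera adjusted p 2.16e-08 (adjusted p = 0.137 with an estimated correlation). Fibroblast and smooth muscle genes fell in 3 of 14 (0 higher and 5 lower adjusted over the list alone, 3 to 5 with 1 array left out), with Pdgfrb (-0.96 ± 0.12) and Mfap4 (-0.73 ± 0.13). The median, -0.50, came with a camera adjusted p of 0.000332 (adjusted p = 0.219 with an estimated correlation). Macrophage and monocyte genes fell in 3 of 18 (0 higher and 6 lower adjusted over the list alone, 2 to 5 with 1 array left out), with Itgax (-0.64 ± 0.12) and Cd68 (-0.61 ± 0.11). Their median was -0.17 and the camera adjusted p 0.0186 (adjusted p = 0.364 with an estimated correlation). Senescence genes fell in 2 of 15 (0 higher and 2 lower adjusted over the list alone, 1 to 3 with 1 array left out, lowest without Zmpste24-/- baseline array 3), with Plau (-0.64 ± 0.10). The median, -0.20, came with a camera adjusted p of 0.0335 (adjusted p = 0.305 with an estimated correlation). Cell cycle genes fell in 2 of 24 (0 higher and 2 lower adjusted over the list alone, 0 to 1 with 1 array left out, lowest without wild type baseline array 1). Their median was -0.20 and the camera adjusted p 0.0121 (adjusted p = 0.497 with an estimated correlation).

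Small nucleolar RNAs, included as a sign of RNA quality, rose in 39 of 73 members and fell in 1 in intact Zmpste24-/- lungs (53 higher and 2 lower adjusted over the list alone), with Snord13 (2.39 ± 0.20), Snora34 (1.71 ± 0.11), Snora15 (1.61 ± 0.14) and Snora73a (1.60 ± 0.12). The median, 0.62, came with a camera adjusted p of 3.74e-36 (adjusted p = 0.0307 with an estimated correlation). Glucocorticoid-induced genes rose in 9 of 17 (12 higher and 1 lower adjusted over the list alone), with Tsc22d3 (0.82 ± 0.12) and Sult1a1 (0.71 ± 0.11). Their median was 0.63 and the camera adjusted p 4.05e-10 (adjusted p = 0.127 with an estimated correlation). Clock genes were higher in 7 and lower in 3 of 16 (10 higher and 3 lower adjusted over the list alone), with Per1 (0.99 ± 0.14), Tef (0.79 ± 0.14) and Cry1 (0.72 ± 0.13). The median, 0.69, came with a camera adjusted p of 0.000369 (adjusted p = 0.137 with an estimated correlation). Heat shock proteins and NRF2 targets each had 1 member higher, of 12 (2 higher and 0 lower adjusted over the list alone, 0 to 1 with 1 array left out, lowest without wild type baseline array 1) and of 14 (1 higher and 0 lower adjusted over the list alone), the latter Gsta4 (0.90 ± 0.13). For heat shock proteins the median was 0.29 and the camera adjusted p 0.0182 (adjusted p = 0.536 with an estimated correlation). For NRF2 targets the median was 0.16 and the camera adjusted p 0.00515 (adjusted p = 0.516 with an estimated correlation). Neutrophil genes had 1 higher of 15 (4 higher and 0 lower adjusted over the list alone, 1 to 5 with 1 array left out), the calcium-binding S100a8 (1.27 ± 0.26). Their median was 0.23 and the camera adjusted p 0.000764 (adjusted p = 0.364 with an estimated correlation). No alveolar type 1 gene of 13 (0 higher and 0 lower adjusted over the list alone), no club or ciliated airway gene of 20 (5 higher and 0 lower adjusted over the list alone) and no adipocyte gene of 10 (0 higher and 0 lower adjusted over the list alone) passed singly, while camera placed these lists higher. With 1 array left out up to 1, 3 and 5 of them passed as higher, the 5 adipocyte genes without Zmpste24-/- baseline array 2. For alveolar type 1 cells the median was 0.18 and the camera adjusted p 0.00201 (adjusted p = 0.384 with an estimated correlation). For club and ciliated airway cells the median was 0.27 and the camera adjusted p 1.02e-05 (adjusted p = 0.384 with an estimated correlation). For adipocytes the median was 0.69 and the camera adjusted p 0.00106 (adjusted p = 0.42 with an estimated correlation). Muscle genes, the red cell and platelet genes and the lamina list did not pass as lists: muscle had 2 higher of 18 (2 higher and 0 lower adjusted over the list alone, 0 to 1 with 1 array left out, lowest without wild type baseline array 1), and red cells and platelets 1 lower of 9 (0 higher and 1 lower adjusted over the list alone), the platelet chemokine Ppbp (-1.33 ± 0.17). For cardiac and skeletal muscle the median was -0.21 and the camera adjusted p 0.681 (adjusted p = 0.838 with an estimated correlation). For red cells and platelets the median was -0.00 and the camera adjusted p 0.718 (adjusted p = 0.838 with an estimated correlation).

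Without wild type baseline array 2, an alternative added after the data were seen, T and NK cell genes were lower in 11 members, B cell genes in 3, collagen and matrix genes in 8, interferon-stimulated genes in 7 and endothelial genes in 3, and small nucleolar RNAs were higher in 36 and glucocorticoid-induced genes in 8. The macrophage list then missed the threshold (camera adjusted p = 0.0721) and the squamous and mesothelial list passed it (0.0498, against 0.206 with all arrays). Without Zmpste24-/- baseline array 1 the lists of NRF2 targets (0.0699), heat shock proteins (0.128), senescence genes (0.0738) and adipocytes (0.0955) missed it. Heat shock proteins (0.0588) and the cell cycle (0.0706) missed it without wild type baseline array 1, and senescence genes without wild type baseline array 3 (0.215). Of all genes, 1399 passed at baseline, 488 higher and 911 lower in Zmpste24-/- lungs, and 95 differed at least 2-fold. The count was 878 without wild type baseline array 2, 906 without Zmpste24-/- baseline array 1 and 646 without Zmpste24-/- baseline array 3.

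**Figure D3:**
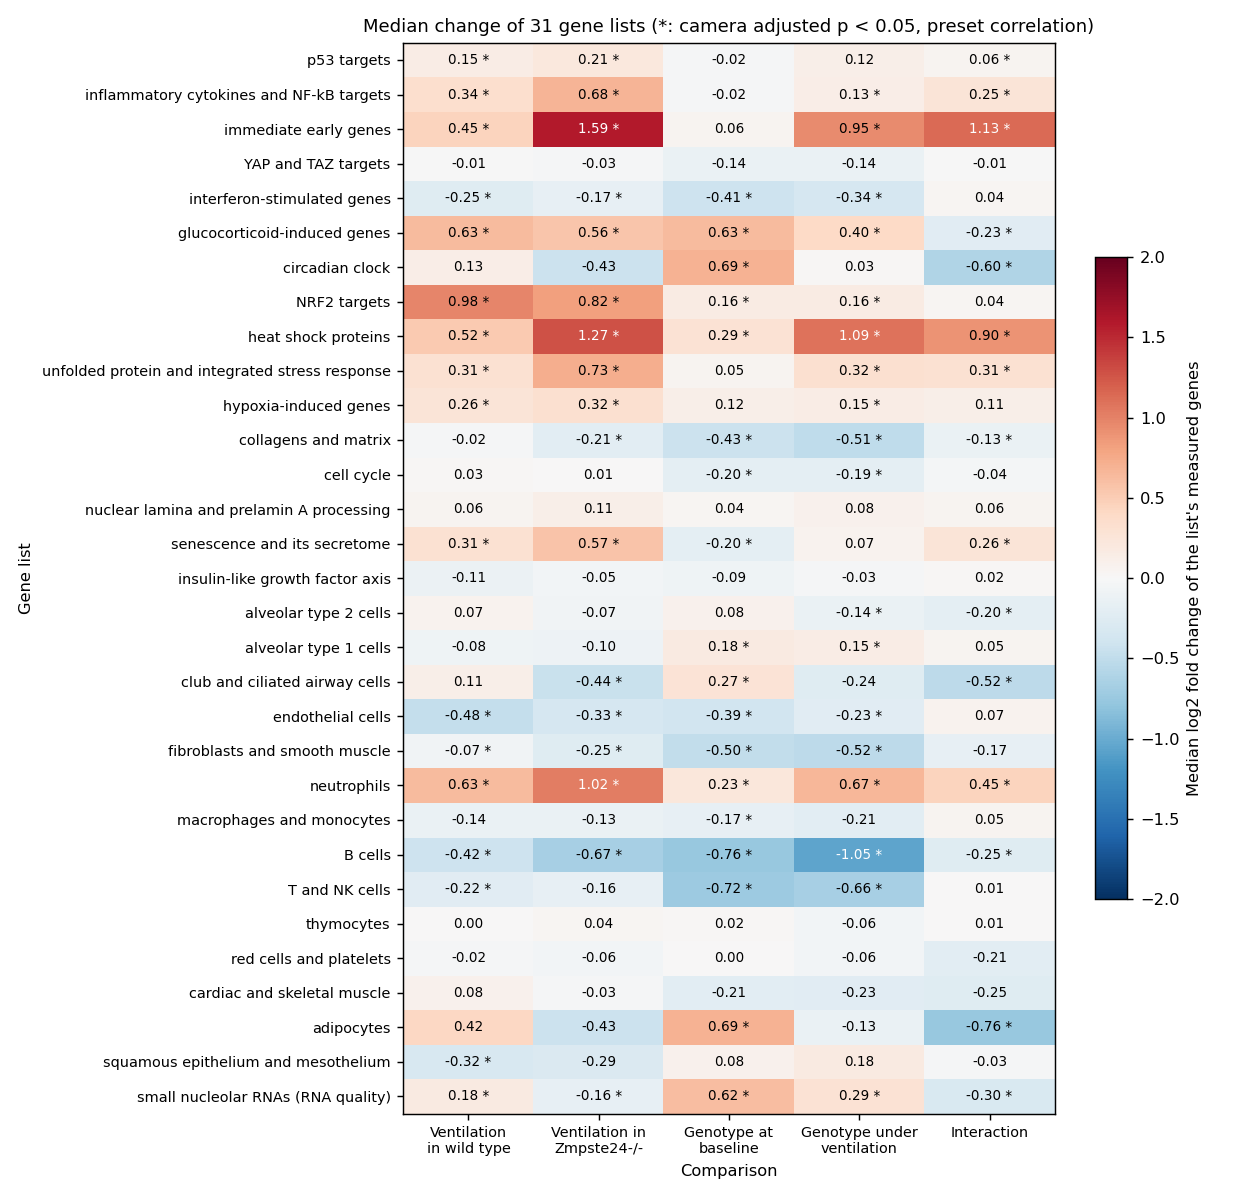
Median log2 fold change (colour and printed value) of the measured genes of 31 fixed lists (vertical axis) in the 5 comparisons (horizontal axis), with asterisks where camera with its preset correlation passed an adjusted p of 0.05. Immediate early genes have the highest median in ventilated Zmpste24-/- lungs, at 1.59, and B cell genes the lowest in the genotype comparison under ventilation, at -1.05.

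Under ventilation, the genotype comparison asked what differed between lungs that had both been ventilated. The largest named increase in Zmpste24-/- lungs was that of Stfa2l1 (3.40 ± 0.37). Immediate early and heat shock genes made up 8 of the other 9: Fosb (2.81 ± 0.36), Nr4a1 (2.14 ± 0.27), Fos (2.05 ± 0.37) and Egr1 (2.00 ± 0.37), all rapidly induced transcription factors, and the chaperones Hspa1b (2.37 ± 0.52), Dnajb1 (2.25 ± 0.22), Hspa1a (2.21 ± 0.40) and Hsph1 (2.01 ± 0.32). Frat2 (2.03 ± 0.17) completed the 10. Hspa1b had its low value of 8.11 in wild type ventilated array 2, against 10.69 and 10.68 in the others. The size of its genotype difference therefore rests in part on that array. Besides Zmpste24, genes of the extracellular matrix were lower, Mmp2 (-2.15 ± 0.17), Col3a1 (-1.95 ± 0.16), Chad (-1.84 ± 0.34) and Col1a1 (-1.72 ± 0.13), with Gzma (-1.64 ± 0.23) and Slamf6 (-1.60 ± 0.14) of lymphocytes and the pseudogene Pisd-ps3 (-2.42 ± 0.30). Ltf (-2.34 ± 0.60) and Actc1 (-1.62 ± 0.41), for lactotransferrin and cardiac actin, were also among the 10, with adjusted p up to 0.0736 and 0.0844 when single arrays were left out. By the naming rule, the arrays of the 2 genotypes did not overlap in any of these genes.

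Immediate early genes were higher in 20 of 22 members in ventilated Zmpste24-/- than ventilated wild type lungs (21 higher and 0 lower adjusted over the list alone), with Ier2 (1.47 ± 0.17) and Klf6 (0.83 ± 0.10). The median, 0.95, came with a camera adjusted p of 8.87e-21 (adjusted p = 0.117 with an estimated correlation). Heat shock proteins were higher in 11 of 12 (11 higher and 0 lower adjusted over the list alone), with Hspe1 (1.18 ± 0.14) and Hsp90aa1 (1.00 ± 0.12). Their median was 1.09 and the camera adjusted p 4.62e-13 (adjusted p = 0.117 with an estimated correlation). Neutrophil genes were higher in 8 and lower in 1 of 15 (8 higher and 1 lower adjusted over the list alone), with S100a8 (1.58 ± 0.26), Clec4d (1.55 ± 0.17) and Mmp8 (1.51 ± 0.27). The median, 0.67, came with a camera adjusted p of 1.72e-07 (adjusted p = 0.133 with an estimated correlation). The unfolded protein and integrated stress response had 7 of 16 members higher (11 higher and 0 lower adjusted over the list alone), with Ppp1r15a (0.93 ± 0.14), Dnajb9 (0.84 ± 0.13) and Ddit3 (0.69 ± 0.08). Their median was 0.32 and the camera adjusted p 1.24e-07 (adjusted p = 0.129 with an estimated correlation). Inflammatory cytokines and NF-kB targets were higher in 8 of 28 (11 higher and 2 lower adjusted over the list alone, 5 to 12 with 1 array left out, lowest without wild type ventilated array 2), with Ccl3 (1.95 ± 0.36), Ptgs2 (1.47 ± 0.27) and Lif (0.96 ± 0.14). The median, 0.13, came with a camera adjusted p of 0.00103 (adjusted p = 0.228 with an estimated correlation). Small nucleolar RNAs were higher in 25 and lower in 1 of 73 (35 higher and 3 lower adjusted over the list alone), with Snord13 (1.73 ± 0.20) and Snord70 (1.63 ± 0.22). Their median was 0.29 and the camera adjusted p 9.53e-12 (adjusted p = 0.133 with an estimated correlation). Glucocorticoid-induced genes were higher in 7 of 17 (11 higher and 0 lower adjusted over the list alone, 3 to 5 with 1 array left out, lowest without Zmpste24-/- ventilated array 2), with Tsc22d3 (0.56 ± 0.12) and Cdkn1c (0.54 ± 0.12). The median, 0.40, came with a camera adjusted p of 3.81e-06 (adjusted p = 0.205 with an estimated correlation). Alveolar type 1 genes were higher in 4 of 13 (5 higher and 0 lower adjusted over the list alone, 2 to 4 with 1 array left out, lowest without Zmpste24-/- ventilated array 2), with Gprc5a (0.46 ± 0.09) and Hopx (0.38 ± 0.09). Their median was 0.15 and the camera adjusted p 0.00226 (adjusted p = 0.371 with an estimated correlation). NRF2 targets were higher in 3 of 14 (3 higher and 0 lower adjusted over the list alone), with Osgin1 (1.28 ± 0.24) and Srxn1 (1.11 ± 0.23). The median, 0.16, came with a camera adjusted p of 0.0176 (adjusted p = 0.575 with an estimated correlation). Hypoxia-induced genes were higher in 3 and lower in 1 of 14 (4 higher and 1 lower adjusted over the list alone, 1 to 3 with 1 array left out, lowest without wild type ventilated array 2), with Adm (1.19 ± 0.17). Their median was 0.15 and the camera adjusted p 0.0112 (adjusted p = 0.255 with an estimated correlation).

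B cell genes were lower in 12 of 12 members in ventilated Zmpste24-/- lungs (0 higher and 12 lower adjusted over the list alone), with Cd22 (-1.51 ± 0.18), Blk (-1.20 ± 0.15) and Fcmr (-1.10 ± 0.16). The median, -1.05, came with a camera adjusted p of 4.62e-13 (adjusted p = 0.129 with an estimated correlation). T and NK cell genes were lower in 15 of 20 (0 higher and 19 lower adjusted over the list alone), with Klrd1 (-1.58 ± 0.18), Cd2 (-0.82 ± 0.09) and Gzmb (-0.77 ± 0.12). Their median was -0.66 and the camera adjusted p 8.24e-15 (adjusted p = 0.0358 with an estimated correlation). Collagen and matrix genes were lower in 13 of 22 (0 higher and 18 lower adjusted over the list alone), with Col1a2 (-1.46 ± 0.09). The median, -0.51, came with a camera adjusted p of 1.35e-14 (adjusted p = 0.0632 with an estimated correlation). Interferon-stimulated genes were lower in 8 of 22 (0 higher and 14 lower adjusted over the list alone, 5 to 11 with 1 array left out, lowest without wild type ventilated array 3), with Oas2 (-1.60 ± 0.12) and Rtp4 (-0.88 ± 0.11). Their median was -0.34 and the camera adjusted p 2.11e-07 (adjusted p = 0.117 with an estimated correlation). Fibroblast and smooth muscle genes were lower in 5 and higher in 1 of 14 (1 higher and 8 lower adjusted over the list alone, 2 to 4 with 1 array left out, lowest without wild type ventilated array 2), with Myh11 (-1.37 ± 0.24) and Pdgfrb (-0.57 ± 0.12) against Tcf21 (0.73 ± 0.11). The median, -0.52, came with a camera adjusted p of 0.00191 (adjusted p = 0.255 with an estimated correlation). Endothelial genes were lower in 4 and higher in 1 of 16 (1 higher and 5 lower adjusted over the list alone, 2 to 4 with 1 array left out, lowest without wild type ventilated array 2), with Emcn (-0.69 ± 0.10) and Tie1 (-0.48 ± 0.08). Their median was -0.23 and the camera adjusted p 0.000257 (adjusted p = 0.263 with an estimated correlation). Cell cycle genes were lower in 5 and higher in 1 of 24 (1 higher and 5 lower adjusted over the list alone, 2 to 5 with 1 array left out, lowest without wild type ventilated array 2), with Kif11 (-0.54 ± 0.11) and Ccnb2 (-0.54 ± 0.10) against Pcna (0.61 ± 0.08). The median, -0.19, came with a camera adjusted p of 0.00692 (adjusted p = 0.438 with an estimated correlation). Alveolar type 2 genes were lower in 2 of 14 (0 higher and 3 lower adjusted over the list alone, 0 to 3 with 1 array left out, lowest without wild type ventilated array 2). Their median was -0.14 and the camera adjusted p 0.0412 (adjusted p = 0.587 with an estimated correlation).

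Of the lists called in the genotype comparison under ventilation, NRF2 targets missed the threshold without wild type ventilated array 2 or Zmpste24-/- ventilated array 2 (camera adjusted p = 0.157 and 0.293), and alveolar type 2 genes without either of these or Zmpste24-/- ventilated array 3 (0.275, 0.108 and 0.177). Alveolar type 1 genes missed it without wild type ventilated array 1 (0.0841) and cell cycle genes without wild type ventilated array 3 (0.102). In that comparison 2395 genes passed, 1046 higher and 1349 lower in Zmpste24-/- lungs, so that 43.7% were higher. With each array's median subtracted, 61.1% of the genes past the threshold were higher. At least 2-fold differences numbered 191, and the total was 1369 without wild type ventilated array 2, 1464 without wild type ventilated array 3 and 1426 without Zmpste24-/- ventilated array 3. Between the genotype comparisons at baseline and under ventilation, which share no arrays, 199 genes were higher in Zmpste24-/- lungs in both (23.0 from independent lists), 433 lower in both (55.4) and 11 opposite (72.6), with Pearson's r of 0.504 and Spearman's rho of 0.437 across genes. The shared estimate of each gene's spread makes the counts from independent lists a low reference here too.

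The interaction tested whether ventilation changed a gene by a different amount in the 2 genotypes, as the change in Zmpste24-/- minus that in wild type lungs. The smallest p belonged to Ahr (1.18 ± 0.12), the aryl hydrocarbon receptor, which fell in wild type lungs (-0.33 ± 0.09) and rose in Zmpste24-/- lungs (0.85 ± 0.09). The same adjusted p of 0.00401 belonged to Adm (2.26 ± 0.25), which rose in both (1.18 ± 0.17 and 3.44 ± 0.17). Map2k3os (1.17 ± 0.13), Brd2 (0.99 ± 0.12), Foxq1 (1.68 ± 0.22), Ier5 (1.10 ± 0.15) and Nfil3 (1.48 ± 0.21) also rose on ventilation in both genotypes and more in Zmpste24-/- lungs. Arntl (2.63 ± 0.37) rose in Zmpste24-/- lungs (2.88 ± 0.26), where its baseline was low, while its wild type change of 0.25 ± 0.26 did not pass. Ccnl1 (0.89 ± 0.12) and Hbegf (1.32 ± 0.19) completed the 10. Of these 10 genes, Ccnl1, Arntl and Hbegf lost their call without Zmpste24-/- baseline array 1 (adjusted p = 0.0514, 0.0514 and 0.0520), and Hbegf also without Zmpste24-/- ventilated array 3 (0.0546).

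Immediate early genes differed in 5 of 22 members, all with the larger change in Zmpste24-/- lungs (17 higher and 0 lower adjusted over the list alone, 0 to 10 with 1 array left out, lowest without wild type baseline array 2), among them Fosb (2.86 ± 0.51), Nr4a1 (2.44 ± 0.39) and Jun (1.28 ± 0.24). The median, 1.13, came with a camera adjusted p of 2.36e-21 (adjusted p = 0.259 with an estimated correlation). Heat shock proteins differed in 2 of 12 (8 higher and 0 lower adjusted over the list alone, 0 to 2 with 1 array left out, lowest without Zmpste24-/- baseline array 1), Dnajb1 (2.14 ± 0.31) and Bag3 (0.97 ± 0.18). Their median was 0.90 and the camera adjusted p 4.83e-10 (adjusted p = 0.259 with an estimated correlation). The unfolded protein and integrated stress response differed in 2 of 16 (7 higher and 0 lower adjusted over the list alone, 0 to 2 with 1 array left out, lowest without wild type baseline array 2), Ppp1r15a (1.08 ± 0.20) and Ddit3 (0.62 ± 0.12). The median, 0.31, came with a camera adjusted p of 2.87e-05 (adjusted p = 0.318 with an estimated correlation). Inflammatory cytokines and NF-kB targets differed in 2 of 28 (8 higher and 0 lower adjusted over the list alone, 0 to 3 with 1 array left out, lowest without wild type baseline array 1), Ccl3 (2.69 ± 0.51) and Nfkbiz (0.85 ± 0.16). Their median was 0.25 and the camera adjusted p 2.87e-05 (adjusted p = 0.259 with an estimated correlation). Among p53 targets 1 of 22 differed (4 higher and 1 lower adjusted over the list alone, 0 to 2 with 1 array left out, lowest without wild type baseline array 2), Btg2 (1.49 ± 0.26), and among clock genes 2 of 16, Nfil3 and Arntl, in a list whose median was negative (4 higher and 10 lower adjusted over the list alone, 1 to 3 with 1 array left out, lowest without Zmpste24-/- baseline array 1). For p53 targets the median was 0.06 and the camera adjusted p 0.049 (adjusted p = 0.346 with an estimated correlation). For circadian clock the median was -0.60 and the camera adjusted p 0.017 (adjusted p = 0.346 with an estimated correlation). Apart from Nfil3, these list members lost their call when some array was left out, with the highest adjusted p, 0.129, for Ddit3 without wild type baseline array 2. The p53 list missed the threshold without 6 of the 12 arrays (camera adjusted p up to 0.159), namely wild type baseline arrays 2 and 3, Zmpste24-/- baseline arrays 2 and 3, wild type ventilated array 1 and Zmpste24-/- ventilated array 2. The clock list missed it without Zmpste24-/- baseline array 1 (0.0634) or wild type ventilated array 1 (0.0807).

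Camera also placed the interaction of club and ciliated airway genes (0 higher and 0 lower adjusted over the list alone), small nucleolar RNAs (0 higher and 6 lower adjusted over the list alone), collagen and matrix genes (0 higher and 7 lower adjusted over the list alone) and alveolar type 2 genes (0 higher and 1 lower adjusted over the list alone) below that of other genes, and neutrophil genes (3 higher and 0 lower adjusted over the list alone) and senescence genes (4 higher and 0 lower adjusted over the list alone) above it, with no single member past the threshold in these lists. For club and ciliated airway cells the median was -0.52 and the camera adjusted p 3.4e-09 (adjusted p = 0.346 with an estimated correlation). For small nucleolar RNAs the median was -0.30 and the camera adjusted p 8.36e-11 (adjusted p = 0.259 with an estimated correlation). For collagens and matrix the median was -0.13 and the camera adjusted p 0.00419 (adjusted p = 0.461 with an estimated correlation). For alveolar type 2 cells the median was -0.20 and the camera adjusted p 0.00419 (adjusted p = 0.651 with an estimated correlation). For neutrophils the median was 0.45 and the camera adjusted p 0.00419 (adjusted p = 0.512 with an estimated correlation). For senescence and its secretome the median was 0.26 and the camera adjusted p 0.00419 (adjusted p = 0.259 with an estimated correlation). Alveolar type 2 genes missed the threshold without wild type baseline array 1 (0.15) or wild type ventilated array 2 (0.0727), and neutrophil genes without Zmpste24-/- baseline array 3 (0.0595). In all 70 genes passed, 59 higher and 11 lower, and 33 differed by at least 2-fold. The count was 8 without Zmpste24-/- baseline array 1, 13 without Zmpste24-/- ventilated array 3, 16 without wild type ventilated array 3 and 17 without wild type baseline array 2. It was 18 without wild type ventilated array 2 or Zmpste24-/- baseline array 2, 21 without wild type baseline array 3 or Zmpste24-/- baseline array 3, 26 without Zmpste24-/- ventilated array 2 and 118 without wild type baseline array 1. With all 41345 probes tested 4 passed, with the median filter 152 and with a second quantile normalization 26.

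Of the 85 list calls made by camera with its preset correlation over the 5 comparisons, 3 held with an estimated correlation: the T and NK cell genes in both genotype comparisons and the small nucleolar RNAs at baseline. In the lists that passed, the median, the mean and camera's direction had the same sign. They differed in sign in lists that did not pass: YAP and TAZ targets, thymocytes, red cells and platelets and the lamina list in more than 1 comparison, collagens and matrix in ventilated wild type lungs, and NRF2 targets, fibroblasts and smooth muscle and squamous epithelium in the interaction.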

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

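The tests of the clock genes below were chosen, with their thresholds, after the values had been seen, as was the look at which arrays the other splits exchange; the count of other splits and the list tests were planned. The interaction stands out because ventilation changed 70 genes by different amounts in the 2 genotypes, by a direct test of the difference. Its leading genes were Ahr (1.18), Adm (2.26), Map2k3os (1.17), Brd2 (0.99), Foxq1 (1.68), Ier5 (1.10), Ccnl1 (0.89), Nfil3 (1.48), Arntl (2.63) and Hbegf (1.32), given as interaction log2 fold changes. Of the 70 genes, 61 passed for ventilation in Zmpste24-/- lungs and 28 in wild type lungs. Among 100 of the 200 ways to reassign genotype within each condition, 4 gave as many genes, the real one included. The share lay under 0.05 but close to it. Chance cannot be judged from this share, because reassignments can carry the genotype difference common to both conditions into the interaction. The 36 other splits drawn that do not carry it gave 0 genes. They mix the genotypes within each group, which adds to the spread, so they cannot decide it either. The count fell to 8 without Zmpste24-/- baseline array 1. The 3 other splits with as many genes gave 3730, 567 and 72. The first 2 call several times the real count, which points to a structure of the samples: all 3 exchange unequal numbers of arrays between the genotypes in the 2 conditions, so that the genotype difference common to both conditions enters the interaction.

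The gene lists that camera called for the interaction had median interaction log2 fold changes of 1.13 for immediate early genes, 0.90 for heat shock proteins, 0.45 for neutrophils, 0.31 for the unfolded protein and integrated stress response, 0.26 for senescence and its secretome, 0.25 for inflammatory cytokines and NF-kB targets and 0.0604 for p53 targets. Negative medians were found for adipocytes (-0.76), the circadian clock (-0.60), club and ciliated airway cells (-0.52), small nucleolar RNAs (-0.30), B cells (-0.25), glucocorticoid-induced genes (-0.23), alveolar type 2 cells (-0.20) and collagens and matrix (-0.13). With an estimated correlation the adjusted p of these 15 lists lay between 0.259 and 0.694. In fry 0 of the 31 lists passed for the interaction. With the preset correlation and 1 array left out, glucocorticoid-induced genes missed the threshold without 7 of the 12 arrays (adjusted p up to 0.364), p53 targets without 6 (0.159) and B cells without 5 (0.416). The circadian clock (0.0807) and alveolar type 2 cells (0.15) each missed it without 2, and adipocytes (0.119, Zmpste24-/- baseline array 1) and neutrophils (0.0595, Zmpste24-/- baseline array 3) without 1. For glucocorticoid-induced genes these were wild type baseline arrays 1 and 2, Zmpste24-/- baseline arrays 1 and 2, wild type ventilated arrays 2 and 3 and Zmpste24-/- ventilated array 3. For B cells they were wild type baseline array 3, Zmpste24-/- baseline array 2, wild type ventilated arrays 1 and 2 and Zmpste24-/- ventilated array 1.

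Clock genes differed between the genotypes at baseline, with a smaller score difference of the opposite sign under ventilation. At baseline the clock outputs had a median difference of 0.79 over 9 genes in Zmpste24-/- lungs, with 5 past the threshold as higher. The activators had a median of -0.86 over 4 genes, with 3 past it as lower. The mean of outputs minus the mean of activators differed by 1.81. The score differed by -0.74 under ventilation (-0.36 without wild type ventilated array 1), an interaction of -2.55 (-2.17 without that array). The exact permutation p was 0.005, 2-sided, the smallest the 400 arrangements can give. It reassigns genotype in both conditions, so it does not test the interaction alone. No difference of the baseline sign was seen under ventilation. Whether a genotype difference of the clock lasts through ventilation cannot be decided, because no time of collection is given for those lungs either. Under ventilation the medians were -0.11 for the outputs and 0.47 for the activators, and 1 activator was the one gene of both arms past the threshold. Lungs collected at different times of day could give opposite arms as at baseline, but the labels used here give no time of collection, so this and a genotype difference in the clock's response to ventilation cannot be told apart.

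Probes without a gene name here, 16010 of the 41345, carried signal too. In the fit of all probes 209 of them passed for ventilation in wild type lungs, 610 for ventilation in Zmpste24-/- lungs, 650 for genotype at baseline and 978 for genotype under ventilation. For the interaction 0 of them passed in limma, with 1294 at an unadjusted p under 0.05.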

How the results depend on the processing

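Of the tests in this part, those added after the data were seen are the list counts without wild type baseline array 2; the others were planned. Of 399 named gene calls, 313 were kept in every alternative other than leaving out an array or a 2-fold minimum, and 289 when each array was left out. Of 85 list calls, 3 held in camera with an estimated correlation and 52 in fry, where 0 lists passed for the interaction. The other settings applied to all 31 lists and all arrays kept at least 73, and no called list turned its direction. With each array left out in turn 64 of the 85 were kept throughout and 21 were lost without at least 1 array. The largest loss was without Zmpste24-/- baseline array 1, 8 of the calls that use it, against 5 without wild type ventilated array 1 or 2.

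Ventilation in wild type lungs gave 799 to 1307 genes with 1 array left out (1597 with all) and 923 with the 2 groups alone; ventilation in Zmpste24-/- lungs 2432 to 3165 (3641); genotype at baseline 646 to 1314 (1399); and genotype under ventilation 1369 to 2510 (2395). Fewer arrays are then fitted. With a 2-fold minimum the counts were 131, 331, 95, 191 and, for the interaction, 33. The interaction count of 70 ranged from 8 to 118 with 1 array left out. It was 152 with genes under the median left out, where fewer genes are tested, and 4 with all probes, where more are tested. A second quantile normalization gave 26, cyclic loess 34, trend and robust estimation 112 and array weights 164. The cause of these changes was not tested for any of the settings.

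Values that changed sign had not passed in the first place, apart from Top2a. With 1 array left out the ventilation change of Zmpste24 ranged from -0.13 to 0.25 in wild type and -0.33 to 0.028 in Zmpste24-/- lungs, and the baseline genotype difference of Lmna from -0.054 to 0.15. Top2a under ventilation, at -0.67, became 0.25 (adjusted p = 0.226) with probes of several symbols kept, where another probe represents it.

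Replicate numbers are shared between groups in the labels, which do not say that they mark a common litter or day. Over 18 pairs of same-numbered arrays the correlation of deviations from the group means ran from -0.15 to 0.15, 2 pairs were over 0.1 and in 8 pairs an array correlated best with its own number in the other group, against 6 by chance, so the numbers were not taken to pair mice. With the replicate number as a block 1463, 3479, 1358, 2315 and 43 genes passed, the 43 for the interaction, and 23 named calls were lost.

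In each pairwise comparison the 10 splits of 6 arrays into 3 and 3 cannot give a share under 0.05. The real split was the 1 with as many genes, and the highest other split gave 1 gene (0 for genotype under ventilation), against 1597, 3641, 1399 and 2395.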

Other observations

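All tests of explanations in this part were chosen, and their thresholds set, after the values had been explored; the gene lists, the lamina genes included, were fixed before. Genes around the targeted locus on chromosome 4 did not stand out: 3 of the 100 nearest measured neighbours of Zmpste24 differed between the genotypes in the same direction at baseline and under ventilation, against 626 of 22038 other genes (2.84%, Fisher's exact p = 0.763).

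Liver transcripts were highest in wild type baseline array 2. Of 35 liver genes, 80% had their highest value over the 12 arrays there, against 9.72% of all genes and an even share of 8.33%. Fisher's exact p was 1.33e-22, over genes of 1 array, which are not independent. The 9.72% is close to the even share, so genes in general were not highest in that array. The share cannot decide on a general fault, because a fault that lowers values or shifts genes both ways need not change it. Its correlation with wild type baseline array 3, 0.986, was the lowest between arrays of one group. Liver RNA in that sample remains a candidate explanation for its own high values. Alb (11.52), Mup20 (10.05) and Mup3 (8.67) were high there, while Cyp3a11 (3.63, median 3.84 elsewhere) was not. Cyp2e1 (8.79) lay above the median of the other arrays (7.45) but under the highest of them (9.99), and no liver profile on this platform was used. None of the 31 lists holds any of the 35 genes.

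Small nucleolar RNAs were higher in intact Zmpste24-/- lungs, with a list median of 0.62. More transcript of their host genes is argued against for the 60 small nucleolar RNAs with a measured host. The host genes had a median log2 fold change of 0.026, a host counted once for each of its RNAs. Over the 46 distinct hosts it was 0.0206. Of the 60, 52 lay above their host (sign-flip permutation p = 1e-05, the smallest that 100000 resamples can give). That p treats the RNAs as independent, although all were measured in the same mice and some share a host. Neither that p nor the Fisher's exact p that follows measures the spread between mice. Small structured RNAs outside the list, a set from which U3, itself a small nucleolar RNA, was taken out after the result had been seen with no change in the outcome, moved with it (median 0.71, 9 of 15 higher and 0 lower, Fisher's exact p = 2.44e-12), while 478 microRNA genes had a median of -0.05 with 3 higher, at a lower mean signal (4.21 against 8.46). A shift of small structured RNAs, as RNA extraction or labelling could give, goes with the 0.71, but not every RNA of the set moved. Of its small nuclear RNAs at baseline, Rn7sk (0.04), Rnu11 (0.02) and Rnu5g (-0.12) did not pass, while Rnu12 (0.78) did. Guide RNAs of the Scarna family stayed in the set, from Scarna2 (0.28) to Scarna6 (1.92). Such a shift was not separated from a genotype effect on these RNAs. Under ventilation the medians were 0.29 for the list and 0.31 for the others.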
